A study of Mus musculus with 4 samples.

How the data were processed

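Total RNA from the liver of wildtype and Sox17 heterozygous mouse fetuses (C57BL/6, gestation day 17, 2 biological replicates each) was hybridised as biotin-labelled cRNA to 4 single-colour Affymetrix arrays. The labels state that the liver was dissected away from the biliary system before extraction. Whether a replicate was 1 fetus or a pool, and the sex of the fetuses, was not given in the sources used here. The deposited values are probe set intensity values (signals) made with MAS5, per the submitters' processing notes, on a linear scale. On each array the mean after trimming the lowest and highest 2% came to 500, the scaling target seen in the values. MAS5 makes each probe set's signal from its own array, so dim signals carry much noise, and scaling to a common mean removes any difference in total RNA between samples. The brightest signals were 56988 and 56860 on the arrays numbered 1 and 34407 and 32468 on those numbered 2.

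The table held 45101 probe sets, of which 64 control probe sets were left out. Of the 45037 that remained, 34945 had 1 gene symbol in the platform annotation used here, 932 had several and 9160 had none listed. Genes were named only from probe sets with 1 symbol. Signals were taken as log2(signal + 16), so that a fold computed on this scale understates the difference of dim genes. The brighter 50% of probe sets by mean over all arrays were tested, 22519 in all, 20167 of them with 1 symbol, standing for 11691 genes. No further normalization was applied in the main analysis. A linear model with genotype as its only term was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), and p-values were adjusted by Benjamini-Hochberg over all tested probe sets, with a threshold of 0.05. The residual degrees of freedom were 2, to which the prior added 3.24. The mean ± SD given for a gene is over the 2 arrays of a genotype on the linear scale.

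Gene lists of cell type markers and pathways, 41 in all, were written before the data were examined, as were the tests, the rule for named genes and most of the alternatives. Each gene was represented by its brightest tested probe set with 1 symbol. Lists with at least 3 tested members, 40 of them, were tested with limma's camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists. The remaining list, of sex-linked genes, is given as signals per array. The standard error of a list's mean is over its genes and does not measure the spread between animals. With 2 arrays per genotype the p-values of camera at the preset correlation do not account for genes of a list varying together between animals beyond that correlation. The genes named were Sox17, the genes past the adjusted threshold with both pairs in the same direction, members with the smallest p of each list described (up to 4), and the sex-linked genes. Because fewer than 10 genes passed in either direction, 10 per direction were taken by the smaller of their 2 differences between same-numbered arrays, and these are described as values. Alb and Afp were named in addition, after their values were seen.

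The replicate numbers in the labels are shared between the genotypes, and the array names in the labels give same-numbered arrays a common code. Same-numbered arrays deviated together from their genotype means (r = 0.383 across 22519 probe sets). Their hybridisation controls also went together, with BioB signals of 1843 and 1365 on the arrays numbered 1 and 609 and 604 on those numbered 2. The differences between genotypes within the 2 pairs correlated at r = 0.189 across probe sets. A fit with the array number as a block was therefore run as an alternative, and differences within each pair are given. Whether the common code marks a batch was not given in the sources used here. The other alternatives were a pseudocount of 1 or 64, no filter on dim probe sets, the brighter 25% of probe sets, median centring, quantile normalization, leaving out each array in turn, a trended and robust prior, a test without moderation, a 2-fold difference in both pairs without a test, camera with an estimated correlation, fry, and the mean over all probe sets of a gene.

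The code was tested on simulated data for the comparison of 2 wildtype with 2 heterozygous arrays, with 22519 probe sets in each of 10 simulations. Probe sets with log2 differences of 1, 2, 3 and 4 were planted, 500 of each size over the 10 simulations. No effect of the array number was simulated. The limma test called 0.4% of log2 differences of 1, 35.8% of those of 2, 82.2% of those of 3 and 95.4% of those of 4. These rates hold only where that many probe sets differ, since the adjusted threshold is stricter when few do. In the data, Hspa1a and Hspa1b did not pass with log2 differences of 3.98 and 4.29. For lists of 20 genes shifted by 0.5 on the log2 scale, camera with the preset correlation called 50 of 50 and 6 of 350 unshifted lists, camera with an estimated correlation called 0 of 50, and fry called 4 of 50. The simulated probe sets varied independently of each other, so the lists held no correlation between genes. Even in that setting an estimated correlation and fry called few shifted lists, so a failure there does not show that a list is unshifted. The rates of camera with the preset correlation do not carry over to lists whose genes vary together, where unshifted lists may be called more often.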

Results

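Gene expression was measured in the liver of mouse fetuses on day 17 of gestation, in wildtype animals and in Sox17 heterozygous animals of the same stage. Sox17 encodes a transcription factor of the SOX family with known roles in endoderm, the extrahepatic bile ducts and gallbladder, and arterial endothelium. Each genotype was represented by 2 biological replicates, and each replicate by 1 whole-genome Affymetrix array of 45101 probe sets. The comparison addressed which liver transcripts differ between heterozygous and wildtype fetuses. The 4 arrays had been brought to a common level, with a mean signal of 500 on each after the lowest and highest 2% of probe sets were set aside, and their median signals lay between 84.7 and 103. With 2 arrays per genotype, the number of arrays limited the precision of every value below.

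Sox17 signal in heterozygous liver was close to 0.5 of the wildtype level on both of its probe sets. The brighter probe set gave 254 ± 14.0 in wildtype and 132 ± 10.8 in heterozygous liver (mean ± SD, n = 2 each), a ratio of 0.518. The other gave 202 ± 50.2 and 102 ± 3.73, a ratio of 0.505. Both heterozygous arrays lay below both wildtype arrays on each probe set, as they did for 18.6% of all tested genes. The log2 difference was -0.87 on both probe sets, with standard errors of 0.25 and 0.29. Neither difference passed the limma test after adjustment over all probe sets (adjusted p = 0.927 and 0.984). Both probe sets were of moderate brightness, at the 62.8 and 59.3 percentiles of all probe sets. Whether they lie inside the altered part of the gene was not given in the sources used here, so the lower signal checks the genotype labels only if they do.

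**Figure D1:**
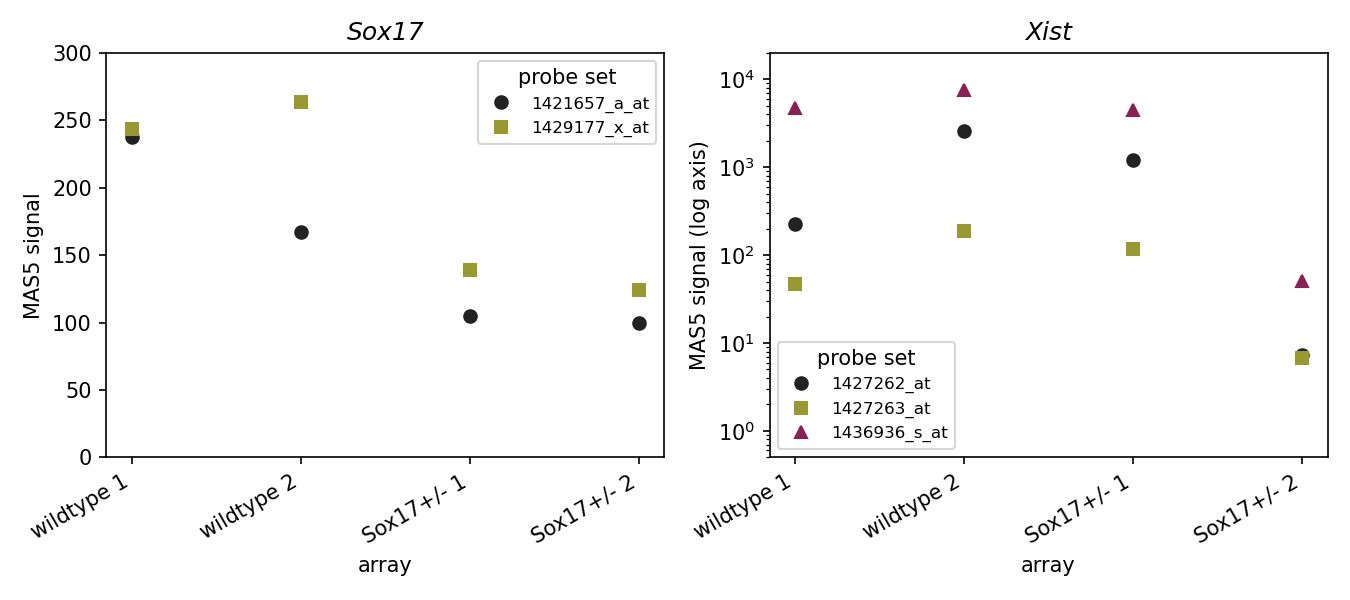
MAS5 signal of the Sox17 probe sets (left, linear axis) and of the Xist probe sets (right, log axis) on each of the 4 arrays, 1 point per array and probe set. Sox17 lay between 99.6 and 139 on the heterozygous arrays and between 167 and 264 on the wildtype arrays, and Xist was at most 50.9 on heterozygous array 2.

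The genes with the largest differences in both same-numbered pairs of arrays are given first on the higher side. Hspa1b and Hspa1a, the inducible HSP70 chaperones, had signals of 2451 ± 990.5 and 1103 ± 255 in heterozygous liver against 105 ± 6.75 and 54.7 ± 14.7 in wildtype (mean ± SD, n = 2 each), which corresponds to 19.6-fold and 15.8-fold on the log2(signal + 16) scale. Cxcl10, an interferon-inducible chemokine, had signals of 5132 and 1215 on the heterozygous arrays against 105 and 191 on the wildtype arrays. Esm1, a secreted proteoglycan of endothelial cells, had 414 ± 67.1 against 20.2 ± 22.9. Ankrd37, a target of hypoxia-inducible factor, had 1312 ± 676 against 164 ± 82.3. The stress-induced transcription factor Atf3 had 475 ± 328 against 58.9 ± 31.4. Hamp, the iron-regulating hormone hepcidin, had the widest spread, with 15330 and 1472 on the heterozygous arrays against 799 and 341. Rgs5, a marker of pericytes, had 291 ± 89.0 against 55.7 ± 31.1, and the potassium channel genes Kcnj8 and Kcne3 had 449 ± 217 against 89.1 ± 77.2 and 424 ± 139 against 60.9 ± 7.74.

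On the lower side, Bhmt, which remethylates homocysteine, had a signal of 3393 ± 151 in heterozygous liver against 15245 ± 7769 in wildtype. Car3, a carbonic anhydrase, had 2936 ± 1141 against 11343 ± 642. Akr1d1, a reductase of bile acid synthesis, had 233 ± 44.3 against 1025 ± 492. The complement component C9 had 384 ± 180 against 1371 ± 927, and the cytochrome P450 Cyp2f2 had 76.1 ± 23.3 against 252 ± 83.9. Sult2a2, a sulfotransferase, had 103 ± 38.3 against 316 ± 30.7. Gdpd5, Cpne2, Tmem25 and Smim27 completed this group, with log2 differences of -1.44, -1.72, -1.44 and -1.49. All 20 genes were taken by the size of the smaller of their 2 pair differences and are given as values.

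**Figure D2:**
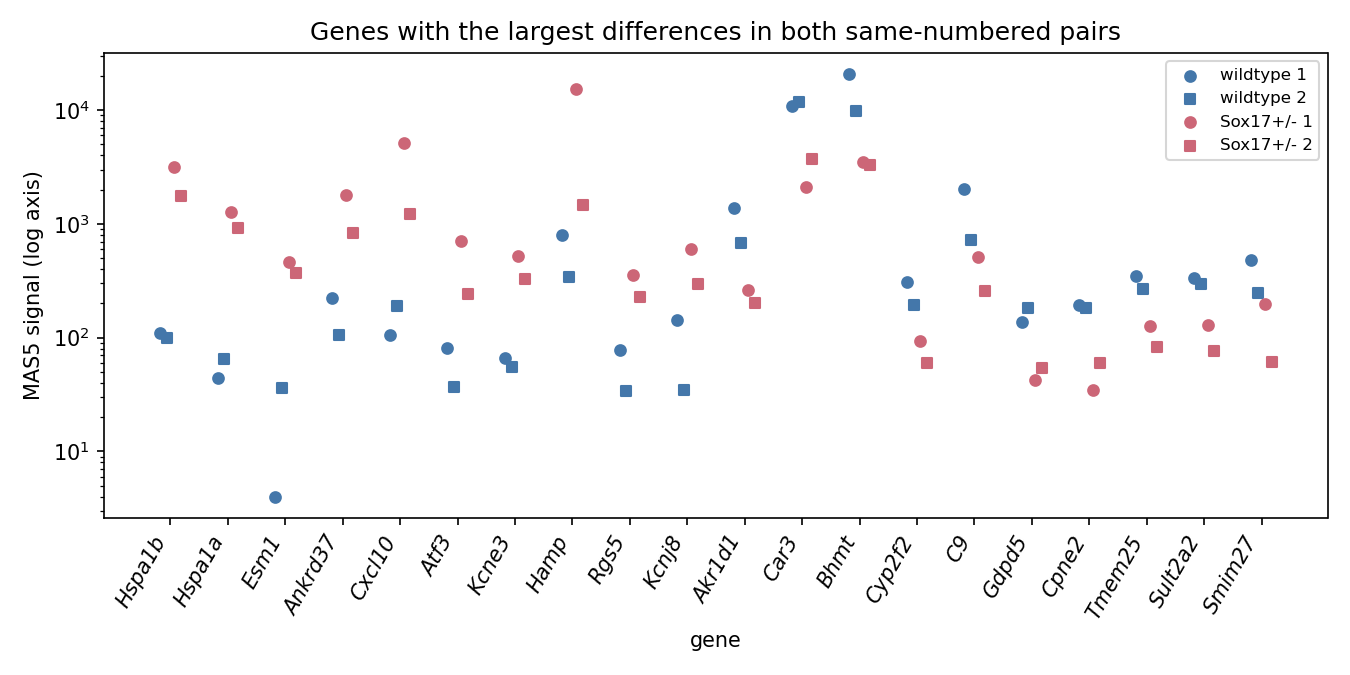
MAS5 signal (log axis) on each of the 4 arrays for the 10 genes with the largest differences upward and the 10 with the largest differences downward in both same-numbered pairs, 1 point per array, circles for arrays numbered 1 and squares for arrays numbered 2. Hspa1b ran from 99.8 and 109 on the wildtype arrays to 1750 and 3151 on the heterozygous arrays.

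No gene passed the test. Of the 22519 probe sets tested with limma, 0 were higher and 0 were lower at an adjusted p under 0.05, and the smallest adjusted p was 0.297, for Hspa1a and Hspa1b. At an unadjusted p under 0.05, 402 were higher and 521 lower, 923 together against the 1126 that chance alone would give. With the array number as a block in the limma fit the unadjusted count was 1693, and 0 passed after adjustment. With each array median-centred, 5 probe sets passed, all higher and belonging to Hspa1a, Hspa1b and Esm1 (smallest adjusted p = 0.00844), and with a trended, robust prior 3 probe sets of Hspa1a and Hspa1b passed (smallest adjusted p = 0.0349). Without a test, 76 probe sets were over 2-fold higher and 44 over 2-fold lower in both pairs, against 7.06 and 7.18 for pairs that moved independently. Probe sets over 2-fold apart in opposite directions were also more than independence gives, 19 higher in pair 1 and lower in pair 2 against 11.6, and 6 the other way against 4.39. An exact permutation test of 2 arrays against 2 cannot give a two-sided p below 0.333. Of the 11691 tested genes, 25.5% were higher in both pairs and 32.2% lower in both, the background for the list counts below.

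Glycolysis and hypoxia genes were higher as a group in heterozygous liver. Of 26 tested members, 24 were higher in both pairs and 0 lower in both, and the mean log2 difference was 0.75 (SE 0.12 over genes), or 1.69-fold. Pfkp, a phosphofructokinase of glycolysis, had a signal of 911 ± 277 against 273 ± 77.6 in wildtype (mean ± SD, n = 2 each). The aldolase gene Aldoa had 13882 ± 3934 against 6214 ± 975, and Vegfa, the angiogenic factor induced by low oxygen, had 1122 ± 164 against 642 ± 23.6. The group passed limma's camera test with its preset correlation (adjusted p = 5.4e-16), but not with an estimated one (adjusted p = 0.80 with an estimated correlation). The median difference was 0.68 within pair 1 and 0.43 within pair 2. Adjusted over the list alone, 2 members passed as higher, against 0 over all probe sets tested.

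Immediate early genes and chemokines were also higher as groups. Of 16 immediate early genes, which respond within minutes to stimulation or stress, 10 were higher in both pairs and 2 lower in both (mean log2 difference 0.66, SE 0.19 over genes, adjusted p = 3.6e-06 by camera). Jun had a signal of 798 ± 363 against 228 ± 25.5, Fos 336 ± 87.6 against 133 ± 8.02, and Ier3 1616 ± 308 against 821 ± 61.5 (mean ± SD, n = 2 each). Of 17 chemokines and inflammatory mediators, 10 were higher in both pairs and 3 lower in both (mean 0.73, SE 0.31, adjusted p = 0.00023). Ccl2, which attracts monocytes, had 488 ± 199 against 97.6 ± 12.2, Cxcl2, which attracts neutrophils, had 360 ± 314 against 24.6 ± 3.87, and the adhesion molecule Icam1 had 1005 ± 264 against 442 ± 1.52. Both groups lost the call when the correlation was estimated (adjusted p = 0.80 with an estimated correlation for each). Adjusted over the list alone, 4 immediate early genes passed as higher, and 5 chemokine genes passed as higher and 1 as lower. The mean of the chemokine group was 0.42 without heterozygous replicate 1. Its call was lost among the brightest 25% of probe sets (mean 0.64, adjusted p = 0.501).

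Of the other stress and metabolic groups, 5 passed on the higher side with smaller means. In the cholesterol synthesis group 12 of 20 members were higher in both pairs (mean log2 difference 0.25, SE 0.07 over genes, adjusted p = 0.00074 by camera), with Cyp51 at 3425 ± 74.8 against 2337 ± 6.62 and Msmo1 at 4873 ± 154 against 3433 ± 232 (mean ± SD, n = 2 each). Without wildtype replicate 2 the cholesterol group had an adjusted p of 0.0582. Among p53 targets and cell death genes 12 of 19 were higher in both pairs (mean 0.38, adjusted p = 0.0022), with the growth arrest gene Gadd45b at 552 ± 239 against 229 ± 47.8 and Plk2 at 717 ± 130 against 417 ± 13.3. That call was lost among the brightest 25% of probe sets (adjusted p = 0.0556). Among NRF2 target genes 8 of 14 were higher in both pairs (mean 0.149, SE 0.155 over genes, adjusted p = 0.030), with the haem oxygenase gene Hmox1 at 8330 ± 1121 against 3605 ± 1900 and the carboxylesterase gene Ces1g in the opposite direction, at 142 ± 37.3 against 407 ± 189. In the unfolded protein response group 8 of 22 were higher in both pairs, 2 lower in both and 12 mixed (mean 0.26, median 0.11, adjusted p = 0.038 by camera). That count is not far from the 25.5% of all tested genes that were higher in both pairs. Its member Atf3, also on the immediate early list, had a log2 difference of 2.60. Sdf2l1 had 1140 ± 250 against 717 ± 300.2, with pair differences of 1.36 and 0.05. The heat shock group (mean 0.66, median 0.02, adjusted p = 0.020) rested on Hspa1a and Hspa1b, and without them its mean over the remaining members was 0.02 (adjusted p = 0.737), with Hspb1 at 169 ± 38.1 against 144 ± 24.7. None of these groups passed with an estimated correlation (adjusted p = 0.80 with an estimated correlation, and 0.82 for heat shock). Adjusted over the list alone, 2 heat shock genes passed as higher and 0 genes of the other 4 groups. The NRF2 call was lost without wildtype replicate 1, wildtype replicate 2 or heterozygous replicate 1 (means 0.15, 0.15 and 0.087, adjusted p = 0.0701, 0.114 and 0.286), and with no filter on dim probe sets (mean 0.057, adjusted p = 0.257). The unfolded protein response call was lost without wildtype replicate 1 or heterozygous replicate 1 (means 0.16 and 0.12, adjusted p = 0.138 and 0.372), while its mean was 0.40 without heterozygous replicate 2 (adjusted p = 0.0019). The heat shock call was lost without wildtype replicate 2 or heterozygous replicate 1 (adjusted p = 0.212 and 0.0891). The unfolded protein response call was also lost with quantile normalization (adjusted p = 0.0776), with no filter (adjusted p = 0.0714) and among the brightest 25% of probe sets (mean 0.13, adjusted p = 0.221). The heat shock call was also lost with no filter (adjusted p = 0.191) and among the brightest 25% (adjusted p = 0.481). The NRF2 mean rose to 0.29 among the brightest 25% (adjusted p = 0.0018 by camera).

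**Figure D3:**
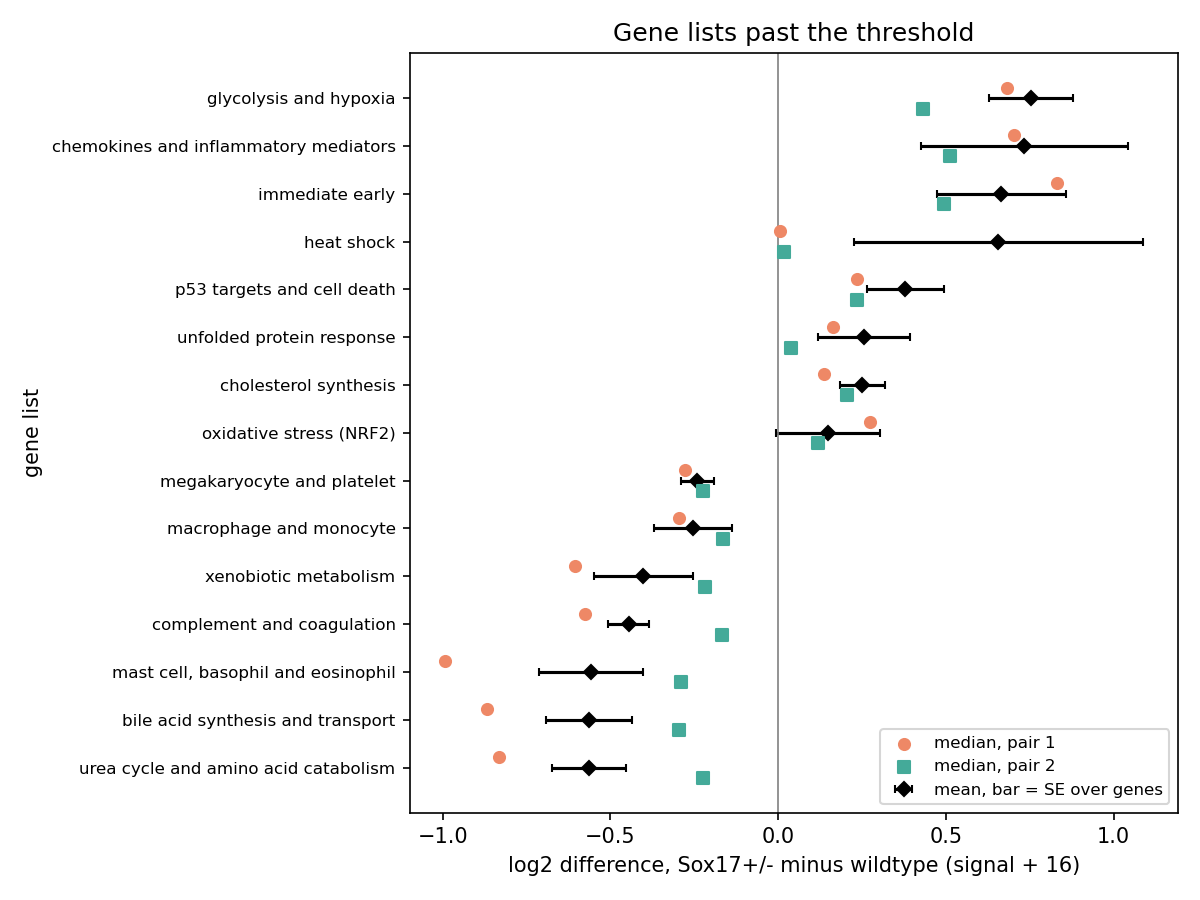
Log2 difference between heterozygous and wildtype liver for the 15 gene lists past the camera threshold with the preset correlation. Diamonds give the mean over the genes of a list with its standard error over genes, and circles and squares the median within the arrays numbered 1 and those numbered 2. The bile acid, urea cycle, complement and xenobiotic lists lay lower in pair 1 (medians -0.58 to -0.87) than in pair 2 (medians -0.17 to -0.29).

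Bile acid, urea cycle and amino acid, complement and coagulation, and xenobiotic genes were lower as groups. Over all tested genes, 32.2% were lower in both pairs. Cholesterol synthesis genes were higher, and fatty acid oxidation, gluconeogenesis, lipogenesis and acute phase genes did not pass. In the bile acid group 16 of 20 members were lower in both pairs (mean log2 difference -0.56, SE 0.13 over genes, adjusted p = 2.1e-05 by camera), with Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 96.1 ± 35.6 against 285 ± 181 and the bile salt export pump gene Abcb11 at 419 ± 22.2 against 967 ± 421 (mean ± SD, n = 2 each). In the urea cycle and amino acid group 15 of 19 were lower in both pairs (mean -0.56, SE 0.11, adjusted p = 5.9e-06), with Otc at 2362 ± 315 against 4686 ± 1011 and Hgd at 1652 ± 1.77 against 3008 ± 671. In the complement and coagulation group 23 of 26 were lower in both pairs (mean -0.45, SE 0.06, adjusted p = 3.6e-06), with the clotting factor gene F9 at 629 ± 30.6 against 1009 ± 290.1 and Hc, complement component C5, at 3249 ± 97.7 against 4945 ± 1070. In the xenobiotic group 11 of 18 were lower in both pairs (mean -0.40, SE 0.15, adjusted p = 0.00068), with Cyp3a11 at 2103 ± 109 against 5051 ± 1003 and Fmo5 at 297 ± 6.44 against 576 ± 103. None of the 4 groups passed with an estimated correlation (adjusted p = 0.80 with an estimated correlation for the bile acid group and 0.82 for the other 3). Adjusted over the list alone, 2 xenobiotic genes passed as lower and 0 genes of the other 3 groups. With no filter on dim probe sets the bile acid mean was -0.34 (adjusted p = 0.039 by camera).

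Over the 83 genes of these 4 groups the mean log2 difference was -0.70 within pair 1 and -0.29 within pair 2. Leaving out 1 array leaves the array numbers unequal between the genotypes. An effect of the number therefore also enters the means below. These 4 groups were weaker without wildtype array 1. Without it the means were -0.21 for bile acid, -0.21 for urea cycle, -0.10 for complement and -0.15 for xenobiotic genes, and the adjusted p was 0.0538, 0.0549, 0.327 and 0.215. The xenobiotic call was also lost without heterozygous replicate 2 (mean -0.25, adjusted p = 0.108), and without wildtype replicate 2 all 4 means moved further down, to between -0.66 and -0.92. Wildtype array 1 stood apart in its actin signal, 11909.5 at the 3' end of Actb against 24712 to 35014 on the other 3 arrays, and in its ratio of 3' to 5' Actb signal, 1.95 against 1.20 to 1.43. The same ratio for Tfrc was highest on heterozygous array 1, at 4.31 against 3.38 on wildtype array 1, and was 2.75 on heterozygous array 2 against 2.31 on wildtype array 2, while that for Gapdh lay between 0.807 and 0.853 on all 4 arrays. The abundant hepatocyte markers did not pass as a group (18 tested, mean -0.03, adjusted p = 0.950), but their direction turned with the array left out. They passed as higher without wildtype replicate 1 (mean 0.31, adjusted p = 0.0040) or heterozygous replicate 2 (mean 0.32, adjusted p = 0.0054), and as lower without wildtype replicate 2 (mean -0.36, adjusted p = 0.0088) or heterozygous replicate 1 (mean -0.37, adjusted p = 0.0025). Alb and Afp were among these markers, with log2 differences of -0.00 and -0.05. Of 17 hepatocyte markers outside the 4 groups, only 6 were no brighter than 21390, the brightest gene of those groups. The highest signals on the arrays numbered 2 were 34407 and 32468. Many of these markers therefore lay in the upper part of the range there. Whether this limited their differences was not tested, so a mean near 0 says little about hepatocyte content.

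Markers of 3 groups of blood cells were lower, against a background of 32.2% of all tested genes lower in both pairs. In the megakaryocyte and platelet group 10 of 12 members were lower in both pairs (mean log2 difference -0.24, SE 0.05 over genes, adjusted p = 0.011 by camera), with Ppbp at 10080 ± 516 against 12597 ± 603 and Gp1bb at 960 ± 71.0 against 1248 ± 67.2 (mean ± SD, n = 2 each). In the macrophage and monocyte group 13 of 19 were lower in both pairs (mean -0.25, SE 0.12, adjusted p = 0.030). Its members diverged, with the Kupffer cell genes Vsig4 at 162 ± 45.0 against 587 ± 316 and Clec4f at 445 ± 59.6 against 841 ± 363, and the scavenger receptor gene Marco in the opposite direction, at 4149 ± 1237 against 1997 ± 367. In the mast cell, basophil and eosinophil group 4 of 6 were lower in both pairs (mean -0.56, SE 0.15, adjusted p = 0.048), with the mast cell protease gene Cpa3 at 80.4 ± 49.5 against 165 ± 3.15. None passed with an estimated correlation (adjusted p = 0.80 with an estimated correlation, and 0.87 for macrophages), and 0 members passed when adjusted over the list alone. The megakaryocyte call was lost without wildtype replicate 1, wildtype replicate 2 or heterozygous replicate 1 (means -0.23, -0.25 and -0.18). The macrophage call was lost without wildtype replicate 1 or heterozygous replicate 2 (means -0.10 and -0.17, adjusted p = 0.418 and 0.406), while its mean was -0.41 without wildtype replicate 2 (adjusted p = 0.0030). The mast cell call was lost without wildtype replicate 2 or heterozygous replicate 1 (means -0.57 and -0.28, adjusted p = 0.108 and 0.296). The mast cell call was also lost with a pseudocount of 1 (mean -0.61, adjusted p = 0.0555) and with quantile normalization (mean -0.53, adjusted p = 0.0902). With no filter on dim probe sets it was lost as well (mean -0.21, adjusted p = 0.796). The macrophage call was also lost with no filter (adjusted p = 0.0941) and among the brightest 25% of probe sets (mean -0.12, adjusted p = 0.221).

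The groups closest to the known sites of Sox17 action did not pass. Of 17 tested SOX and Notch genes, 6 were higher and 7 lower in both pairs (mean log2 difference -0.01, adjusted p = 0.737 by camera). Endothelial genes had a mean of 0.07 over 22 members (adjusted p = 0.134), and cholangiocyte and ductal plate genes 0.08 over 12 members (adjusted p = 0.737). Gallbladder, gut and pancreas epithelial genes had a mean of -0.29 over 7 members, with 5 lower in both pairs (adjusted p = 0.0944, and 0.0491 with the array number as a block). That call did not hold in the blocked fit either once the correlation was estimated (adjusted p = 0.79 with an estimated correlation). Matrix and stellate cell genes had a mean of 0.12 over 23 members (adjusted p = 0.0574), lymphoid genes -0.26 over 13 (adjusted p = 0.0574), and fatty acid oxidation genes -0.19 over 21 (adjusted p = 0.0973). Endothelial genes passed as higher when all probe sets of a gene were averaged (adjusted p = 0.0256) and without wildtype replicate 1 (mean 0.18, adjusted p = 0.0143), and fatty acid oxidation genes as lower among the brightest 25% of probe sets (adjusted p = 0.0069). The remaining groups were further from the threshold, although leaving out a single array brought several of them past it. Their mean differences were 0.09 for ribosomal proteins, 0.11 for interferon response, 0.25 for skeletal muscle, 0.58 for embryonic globins, 0.02 for proliferation, 0.01 for neutrophils, -0.06 for the respiratory chain, -0.14 for gluconeogenesis, 0.14 for acute phase, 0.33 for iron handling, -0.00 for erythroid, 0.00 for lipogenesis, 0.06 for mesothelium, 0.04 for fetal growth factors, -0.00 for haem synthesis, -0.00 for haematopoietic progenitors and 0.01 for circadian clock genes. The median was below 0 where the mean was above 0 for acute phase (-0.09), iron handling (-0.02), lipogenesis, fetal growth factors and circadian clock genes, and above 0 where the mean was below it for erythroid and haem synthesis genes. The camera test pointed upward, against a mean below 0, for SOX and Notch, erythroid, haem synthesis and haematopoietic progenitor genes, and downward, against a mean above 0, for circadian clock genes.

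Xist, the RNA that coats an inactive X chromosome, was low on 1 array. Its brightest probe set had signals of 4681 and 7608 on the wildtype arrays, 4459 on heterozygous array 1 and 50.9 on heterozygous array 2. The other 2 Xist probe sets were also lowest on that array. These 2 were next lowest on wildtype array 1, at 226 and 46.7. Wildtype array 2 had 2618 and 187, and heterozygous array 1 had 1212 and 118. The 9 probe sets of the Y-linked genes Eif2s3y, Kdm5d and Uty reached at most 55.6 on any array. The Xist difference between genotypes did not pass (log2 difference -3.45, SE 2.04, adjusted p = 0.9997).

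The arrays also resembled each other by replicate number. Over the 22519 tested probe sets, the log2 signals of the arrays numbered 2 correlated at r = 0.978 across genotypes and those numbered 1 at 0.963, against 0.955 between the wildtype arrays and 0.968 between the heterozygous arrays. These correlations run across probe sets, which are not independent replicates. Dividing the arrays by number instead of genotype called 0 probe sets at an adjusted p under 0.05 and 3028 at an unadjusted p under 0.05, and 19 of 40 lists by camera, against 15 lists by genotype. The glycolysis and hypoxia list was among the 19, with a mean log2 difference of -0.43 for the arrays numbered 2 against those numbered 1 (adjusted p = 0.0029). The remaining division of the 4 arrays called 1 list and 319 probe sets unadjusted. Camera with its preset correlation therefore also called the structure by array number.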

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

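The counts of probe sets over 2-fold in both pairs under other settings, and the heat shock list without its HSP70 genes, were chosen after the data were seen. The glycolysis and hypoxia list and the immediate early list kept their direction and their side of the threshold under all 12 alternatives that used camera with the preset correlation (means 0.51 to 0.996 and 0.45 to 0.88). Sox17 stayed lower on both probe sets under every alternative (log2 differences -1.10 to -0.63 and -0.95 to -0.70) without passing under any. Both heterozygous arrays lay below both wildtype arrays, so leaving out an array or changing the pseudocount, filter or test could not turn its sign. With the array number as a block, 0 probe sets passed (smallest adjusted p 0.190, with 1693 at an unadjusted p under 0.05), all 15 list calls were kept and 1 was gained, the gallbladder list; it changed no other call. Where a cause is not named below, the cause was not tested. With 1 array left out of a genotype, the lone array is assumed to vary like the other genotype, and the array numbers no longer balance. The 0 probe sets called became 5 higher with median centring and 3 higher with a trended, robust prior, while the test without moderation called 0, and the criterion of a 2-fold difference in both pairs, which uses no test, took 76 higher and 44 lower. The 76 became 290 with no filter on dim probe sets and 28 in the brightest 25% of probe sets, and the 44 became 437, 12, 21 with a pseudocount of 64 and 27 with median centring; no filter adds probe sets and the 25% leaves fewer. Of the list calls, the 8 higher became 5 with no filter, 4 in the brightest 25% of probe sets and 0 with an estimated correlation or with fry, the 7 lower became 0 with an estimated correlation or with fry, and leaving out 1 array gave 5 to 15 higher and 1 to 13 lower, the 1 without wildtype replicate 1. The correlation of same-numbered deviations was 0.366 with a pseudocount of 1, 0.168 with no filter and 0.372 with quantile normalization, and that of the pair differences 0.177, 0.0420 and 0.202.

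Some lists that did not pass in the main setting changed sign under others, most of them with means near 0. In the brightest 25% of probe sets the means were -0.21 for cholangiocytes, -0.038 for the circadian clock, 0.099 for haematopoietic progenitors and -0.015 for neutrophils. With median centring they were 0.044 for erythroid, 0.044 for haem synthesis, 0.043 for haematopoietic progenitors, 0.021 for hepatocytes and 0.034 for SOX and Notch. With the mean over all probe sets of a gene they were 0.0047 for erythroid, -0.0046 for lipogenesis and 0.031 for SOX and Notch. With quantile normalization they were 0.015 for haematopoietic progenitors, -0.036 for lipogenesis and 0.021 for SOX and Notch. A pseudocount of 1 gave -0.0011 for lipogenesis. No filter on dim probe sets gave -0.11 for lipogenesis, -0.15 for mesothelium and -0.12 for skeletal muscle. Leaving out 1 array in turn gave means of -0.084 to 0.059 for SOX and Notch, -0.33 to 0.61 for acute phase, -0.14 to 0.30 for cholangiocytes, -0.13 to 0.15 for the circadian clock, -0.32 to 1.48 for embryonic globins, -0.045 to 0.18 for endothelium, -0.033 to 0.029 for erythroid, -0.44 to 0.059 for fatty acid oxidation, -0.64 to 0.37 for gluconeogenesis, -0.033 to 0.12 for fetal growth factors and -0.047 to 0.040 for haem synthesis. It gave means of -0.033 to 0.026 for haematopoietic progenitors, -0.37 to 0.32 for hepatocytes, -0.0067 to 0.23 for interferon response, -0.11 to 0.11 for lipogenesis, -0.63 to 0.10 for lymphoid, -0.12 to 0.24 for mesothelium, -0.22 to 0.10 for the respiratory chain, -0.38 to 0.41 for neutrophils, -0.081 to 0.13 for proliferation, -0.21 to 0.39 for ribosomal proteins and -0.025 to 0.53 for skeletal muscle. Lists outside the 15 passed when 1 array was left out, mostly in a direction that followed its number and genotype. The array numbers are then unequal between the genotypes, so a difference between the numbers enters the genotype difference. Hepatocyte, acute phase, neutrophil and ribosomal means were above 0 without wildtype replicate 1 or heterozygous replicate 2. They were below 0 without wildtype replicate 2 or heterozygous replicate 1. A difference between the array numbers gives that pattern, so these calls do not show a genotype difference. Without wildtype replicate 1, 8 passed, all higher (acute phase, endothelium, gluconeogenesis, hepatocytes, interferon response, neutrophils, ribosomal proteins and matrix). Without heterozygous replicate 2, 7 passed, all higher (acute phase, cholangiocytes, hepatocytes, interferon response, iron handling, neutrophils and ribosomal proteins). Without wildtype replicate 2, 7 passed, embryonic globins as higher and 6 as lower (acute phase, fatty acid oxidation, gluconeogenesis, hepatocytes, lymphoid and the respiratory chain). Without heterozygous replicate 1, 8 passed, all lower (acute phase, fatty acid oxidation, gallbladder, hepatocytes, lymphoid, the respiratory chain, neutrophils and ribosomal proteins). With all arrays, lymphoid genes passed as lower with a pseudocount of 64, with no filter and with median centring (adjusted p = 0.0497, 0.0352 and 0.0387), gallbladder genes as lower with no filter (adjusted p = 0.0223), and matrix genes as higher with a pseudocount of 64 and with the mean over all probe sets (adjusted p = 0.0497 and 0.0273). Of the 70 named genes followed, 4 changed sign, with ranges of -0.015 to 0.41 for Hspb1, -0.032 to 0.76 for Hspb8, -1.48 to 0.15 for Mcpt8 and -0.19 to 2.43 for Sesn2. Of the 40 lists, 18 kept 1 sign throughout.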

Other observations

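The tests of handling, of hepatocyte share, of scaling of the hypoxia genes and of an XY embryo were chosen after the results they measure had been seen.

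The following genes of blood vessels and iron handling, outside the groups that passed, were picked after their values were seen. Hey1, a Notch target of arterial endothelium, had a mean signal of 70 in heterozygous liver against 135 in wildtype (log2 difference -0.82, lower in both pairs). Sox18 and Sox7, the other SOX factors of the same subfamily as Sox17, had log2 differences of 0.46 and 0.40. The intermediate filament gene Des, a marker of stellate cells and pericytes, had 223 against 97 (log2 difference 1.11, higher in both pairs). Hamp2, a second hepcidin gene, had 363 against 50 (log2 difference 2.51), with pair differences of 4.32 and 0.70, and the BMP-responsive genes Id1 and Smad7 had log2 differences of 0.84 and 0.87, with a pair 2 difference of only 0.13 for Id1. The iron handling list went both ways, with 5 of 15 members higher and 7 lower in both pairs, among the lower ones the hepcidin regulators Hfe (-0.36), Tmprss6 (-0.56), Hjv (-0.42) and Tfr2 (-0.57). None of these passed the adjusted threshold.

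Hypoxia and glycolysis genes were higher in heterozygous liver. They also differed by array number (mean -0.43 for the arrays numbered 2, adjusted p = 0.0029 by camera), and each genotype holds 1 array of each number, so an additive effect of the number cancels from the genotype difference by design and was not tested as its cause. Quantile normalization left the mean difference at 0.75. The arrays already had a common trimmed mean and close medians (84.7 to 103). Quantile normalization could therefore change little, and it is a weak test of array scaling. A longer interval or more stress between death and lysis predicts higher immediate early genes, and their mean difference was 0.66, so handling that differed between genotypes may account for the pattern. A response inside heterozygous fetuses predicts the same value, and no measurement here separates the 2, so genotype stays open as well.

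Bile acid, urea cycle, complement and xenobiotic genes were lower in heterozygous liver, with a mean of -0.49 over the 83 genes of these 4 lists. Without wildtype replicate 1 that mean was -0.16, with the array numbers unequal between the genotypes. Within pair 2, where the numbers are equal, it was -0.29. Quantile normalization left a mean of -0.48, again a weak test of array scaling, since the arrays already had close signal levels. A smaller share of hepatocytes predicts a similar drop in hepatocyte markers outside those lists, which had a mean of 0.072 (SE 0.19 over genes) and of 0.33 without wildtype replicate 1. Only 6 markers were no brighter than the lists' brightest gene, so their error is too wide and their mean too dependent on the arrays used to decide. A smaller hepatocyte share cannot be told apart from lower expression within hepatocytes. Handling and genotype were not separated for these genes.

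Xist was low on heterozygous array 2. A single X chromosome predicts lower levels of genes that escape X inactivation. The median log2 difference of 5 such genes from the mean of the other 3 arrays was -0.24 on that array, against -0.07 to 0.19 on the others. The 5 genes were spread from -0.60 for Kdm6a to -0.06 for Ddx3x, with Kdm5c also near 0 at -0.07. The direction is that predicted by a single X, but so few genes with this spread are weak evidence for it. Lost silencing of a second X chromosome predicts higher X-linked genes, but the median over 37 such genes was 0.023 (95% bootstrap interval -0.040 to 0.15). An XY embryo predicts Y-linked probe sets brightest on that array, but 0 of 9 were, and the highest there was 36.3. All stayed at or below 55.6 on every array, so no array showed that these probe sets would detect a Y chromosome. An XY embryo was therefore neither borne out nor excluded. An embryo with a single X and no Y could not be told apart from it. The labels do not state the sex, and whether it differed between the heterozygous replicates stays open.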
